A study of Schizosaccharomyces pombe with 22 samples.

How the data were processed

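Chromatin immunoprecipitation followed by hybridisation to a tiling array (ChIP-chip) was carried out in fission yeast, Schizosaccharomyces pombe, on 22 arrays. Of these, 12 arrays measured GFP-tagged subunits of the rixosome, a ribosome biogenesis complex, and 10 arrays measured trimethylated lysine 9 of histone H3 (H3K9me3), the histone mark of heterochromatin. Per the labels' protocols, cells came from logarithmic cultures in rich medium, and the GFP cultures were held at a lower temperature and given a second crosslinker before lysis. On every array the immunoprecipitated DNA carried Cy5 and whole-cell extract DNA of the same strain carried Cy3, per the labels' protocols, with no dye swap, so a dye effect cannot be separated from enrichment on single arrays.

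The values were made with Agilent Feature Extraction version 12.0.3.1, per the file headers. Processed signals are spot intensities from which local background and spatial trend were subtracted and which were linearly dye-normalized, per the file headers. The median spot and local background signals are uncorrected intensities, per the file headers. The deposited log ratio column is a log10 of the red (Cy5) over the green (Cy3) processed signal. The deposited series matrix holds linear ratios of the same processed signals: its 41361 entries per array lay within a relative gap of 4.45e-09 of Cy5 over Cy3 computed here, which settled their scale and direction and showed that they were not centred. Their medians per array were 0.948 to 1.06. No genome build is named in the headers, so positions are those of the array's tiles, and no position was moved to or from another build.

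Each array held 42968 spots, of which 41551 were not controls; 18457 of these lay on chromosome I, 14836 on II and 7958 on III, with 110 on a separate mating-type contig, 61 on the mitochondrial genome and 129 on tiles named pNSU. Median signal over local background was 144 to 233 for Cy3 (median over arrays 191) and 36.7 to 112 for Cy5 (median 74.5). The share of spots well above background was lowest at 99.8% over all arrays and both channels, and 0 spots were saturated; between 0 and 1103 spots per array carried an outlier mark and were left out. The number of arrays limits the precision, and for H3K9me3 so do differences between slides. The log2 ratio of processed Cy5 over processed Cy3 was centred on each array's median, which before centring lay between -0.08 and 0.09. No loess, quantile or spread scaling was applied, because broad domains truly differ in ChIP.

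Probe values were averaged in 1-kb windows holding at least 2 probes, which gave 12411 windows for GFP and 12380 for H3K9me3. Differences were tested with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes, Benjamini-Hochberg adjustment, threshold 0.05). All adjusted p-values of windows are limma's, and those of regions are from limma's fry, whose PValue tests whether the windows of a region move one way on balance. Region p-values were adjusted over 15 region sets per comparison, and those of the 30-kb flanks described below over the 4 flanks only. The GFP model held the tagged protein (4 levels) and the genotype (3 levels) over 12 arrays, so the 4 proteins act as the repeats of a genotype, with 6 residual and 5.57 prior degrees of freedom. The H3K9me3 model held the mean of each of 8 genotypes over 10 arrays. Its 2 residual degrees of freedom (5.69 prior) come only from the pairs of wild-type (WT) and ago1D arrays, and genotypes with 1 array are assumed to vary like these. Interactions compare the effect of a mutation on the log2 ratio in ago1D cells with its effect in otherwise wild-type cells. The labels do not state that replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

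The regions, the tests, the rule for named windows and the other settings to try were fixed before the data were examined. Regions were the pericentromeres (cen1, I 3750 to 3800 kb; cen2, II 1600 to 1650 kb; cen3, III 1070 to 1140 kb), the mating-type locus (II 2110 to 2140 kb), the terminal 50 kb of each end of I and II as subtelomeres, 50 to 100 kb from those ends as distal subtelomeres, and the terminal 25 kb of III. The regions had been set for a named build, and they were applied to the tile positions unchanged. The mating-type contig, flanks of 30 kb on each side of a region and isolated peaks more than 30 kb from any region were added after the data were seen. Named windows were the 10 most negative and 10 most positive differences among those past the threshold and, for GFP, moving the same way with all 4 proteins; where none passed, the 3 most extreme on each side are given and not called changed. This rule, the gene values and the gene lists had been written for genes. Without a named build or probe sequences, gene values, gene lists and the restriction to uniquely matching probes were not run, and the rule was applied to windows. Outer repeats of the pericentromeres are near-identical, so a probe there can report several copies.

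Slides and scans were read from the files and numbered. With GFP, slide 1 held the 3 Las1-GFP arrays, slide 2 the Ipi1-GFP arrays and slide 3 the Crb3-GFP arrays, while the GFP-Rix1 arrays lay on slide 4 (WT) and slide 5 (swi6-115 and clr4D). With H3K9me3, slide 6 held WT replicate 1, ago1D replicate 1, rix1E414K and rix1E414K-ago1D; slide 7 held amo1D and amo1D-ago1D; slide 8 held WT replicate 2, ago1D replicate 2, pob3D and pob3D-ago1D. Values with the slide as a block and within each slide were therefore computed. The slide-blocked H3K9me3 fit leaves 1 residual degree of freedom. It gives no value for amo1D against WT or for amo1D-ago1D against ago1D, which cannot be told apart from slide 7, but it gives one for their interaction. For 4 GFP arrays against 4, all splits of the 8 arrays were refitted, and the real split was set against those with 1 array of each tagged protein per side, since the proteins pair the arrays.

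The fit was tested on simulated data in which 200 windows were shifted. All windows at the left end of I were shifted too, by 0.5 log2 for swi6-115 against WT and by 1.5 log2 for the H3K9me3 comparisons. Calls there are in the totals below but count as neither recovered nor false. For swi6-115 against WT, 100% of windows shifted by 0.5 log2 were recovered, with 16 false among 242 calls. For ago1D against WT, 18% of windows shifted by 1 log2 and 100% of those shifted by 3 log2 were recovered, with 10 false among 164 calls. For amo1D against WT the shares were 5% and 100%, with 9 false among 141 calls, and for the interaction of amo1D and ago1D 2% and 92%, with 16 false among 119 calls. The false share was above 0.05 in all 4 simulations and highest for the interaction. The H3K9me3 comparisons thus have little power for changes of 1 log2 unit or less. With fry the shifted end of I passed the threshold for swi6-115, ago1D and amo1D, but the shift of 1.5 log2 was missed for the interaction. A region that does not pass below is therefore not shown to be unchanged. The 200 shifted windows lay outside the fixed regions, and the noise of each window was drawn independently. Recovery of single windows inside the heterochromatin regions was therefore not tested, and the shares at 3 log2 do not carry over to them. Alternatives were normexp background correction (offset 50), the series matrix values, no centring, spread scaling, a filter on dim probes, 3-kb windows, no protein term, fewer arrays, each tagged protein left out in turn, each WT and each ago1D array of the H3K9me3 ChIP left out in turn, slide and replicate blocks, other enrichment thresholds (0.58 and 1.58) and the terminal 30 kb as subtelomeres. After the data were seen, 4 further alternatives were added: the ChIP channel alone, the ChIP channel alone with the slide block, removal of windows over intervals lost from the extract, and removal of the array labelled amo1D. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.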

Results

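The series follows heterochromatin in fission yeast, where H3K9me3 covers the pericentromeres, the silent mating-type locus and the subtelomeres. Its title concerns the positioning of heterochromatin at the nuclear periphery by Amo1 and the inheritance of the silent state. Of the 22 arrays, 12 mapped GFP-tagged Rix1, Las1, Ipi1 and Crb3, all rixosome subunits, in wild-type (WT) cells and in swi6-115 and clr4D mutants, with 1 array per protein and genotype. The other 10 arrays mapped H3K9me3 in WT (2 arrays), ago1D (2 arrays), and 1 array each of amo1D, rix1E414K, pob3D and the double mutants amo1D-ago1D, rix1E414K-ago1D and pob3D-ago1D. Clr4 is the H3K9 methyltransferase, Swi6 is an HP1 protein that binds methylated H3K9, Ago1 is the Argonaute protein of the RNA interference pathway, and Pob3 is a subunit of the histone chaperone FACT. All ratios are log2 of immunoprecipitated DNA over whole-cell extract, relative to the array median, at tile positions of the array, whose genome build is not given in the sources used here. Signal exceeded local background by a median factor of 74.5 for the ChIP channel and 191 for the extract.

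The deleted genes were checked first, in the extract channel. An interval at II 457500 to 458760 was lost in the 4 clr4D arrays, at -10.15 to -9.06 relative to other arrays, while no other array fell below -0.17. An interval at III 333900 to 336960 was lost in the 5 arrays whose label holds ago1D (-8.58 to -7.70), and one at II 3171900 to 3172260 was lost in both arrays whose label holds pob3D (-10.46 and -9.72). An interval at II 3030300 to 3031860 was lost in amo1D-ago1D (-9.26) and, less deeply, in amo1D (-5.60). These intervals are taken here as clr4, ago1, pob3 and amo1 because they were lost in the arrays with those labels and in no others. In the ChIP channel, the array labelled amo1D stood at -0.57 over the amo1 interval, inside the range of the 20 arrays without the loss (-0.83 to -0.32). The other 24 combinations of an array and an interval with lost extract had ChIP signal between -8.94 and -4.19. The extract and the ChIP DNA on this array therefore disagree about amo1, and it is called the array labelled amo1D throughout. For rix1E414K, which is a point change, and for swi6-115, where no interval was lost, the arrays check nothing. All 10 H3K9me3 arrays also lacked II 2133000 to 2133960 in the mating-type locus, which every GFP array kept, and the GFP-Rix1 WT array alone lacked II 2808600 to 2809260 and II 4287600 to 4288260.

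**Figure D1:**
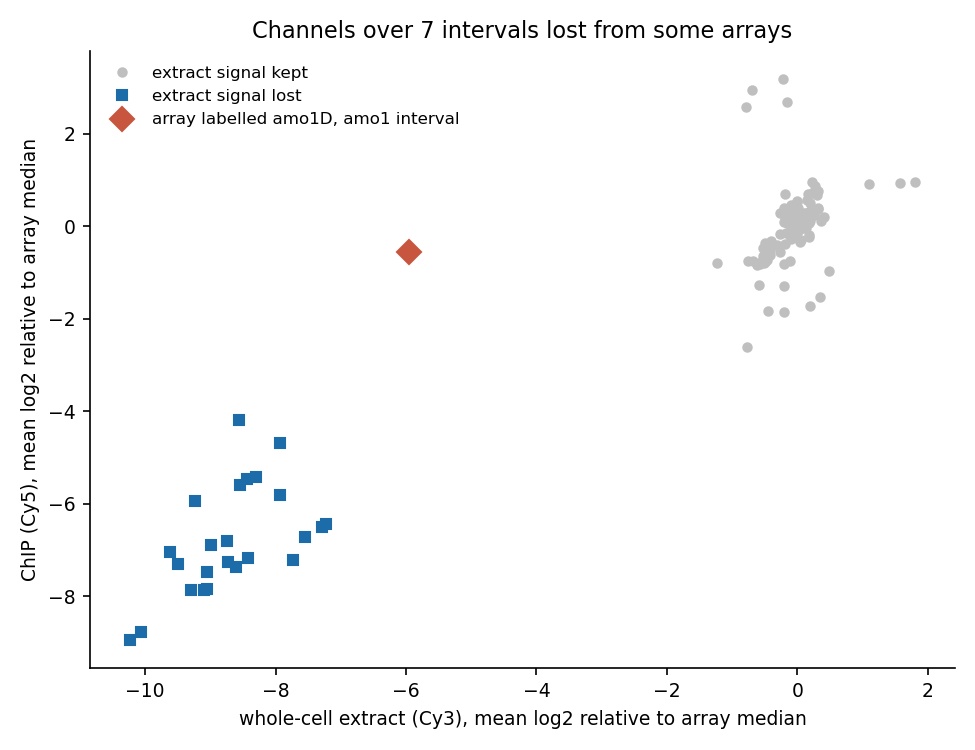
Mean log2 signal relative to the array median in the whole-cell extract (Cy3, horizontal axis) and the ChIP (Cy5, vertical axis) for every array over each of 7 intervals lost from some arrays. Grey circles are combinations with the extract signal kept, blue squares those with it lost, and the red diamond is the array labelled amo1D over the amo1 interval, at -5.95 in the extract and -0.57 in the ChIP.

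In WT cells the GFP signal of the rixosome subunits lay on heterochromatin. The series holds no GFP ChIP of an untagged strain. Signal that remained in swi6-115 or clr4D therefore cannot be told from background. The mean GFP ratio over the 4 proteins was 1.67 ± 0.44 at the pericentromeres, 1.52 ± 0.24 at the mating-type locus and 2.06 ± 0.29 on the mating-type contig (SD, n = 4 arrays, 1 per protein). At the ends of chromosome I it was 1.33 ± 0.44 (left) and 1.59 ± 0.95 (right), whereas the ends of chromosome II stood at -0.09 and 0.02. The rest of the genome averaged 0.02. A ratio of at least 1 on all 4 arrays covered 120 kb, of which 109 kb (90.8%) lay inside the fixed regions and the mating-type contig: 17 kb in cen1, 17 kb in cen2, 21 kb in cen3, 11 kb in the mating-type locus, 19 kb on the mating-type contig, 15 kb at the left end of I and 9 kb at its right end. In swi6-115 the same threshold was met on all 4 arrays by 2 kb, and in clr4D by 5 kb. Single arrays met it over 209 to 297 kb in WT, 87 to 163 kb in swi6-115 and 16 to 195 kb in clr4D. Of these, 138 to 193, 19 to 44 and 8 to 26 kb lay inside the fixed regions and the mating-type contig. The extents on all 4 arrays depend on the threshold. At 0.58 they were 199 kb in WT (63.8% inside), 103 kb in swi6-115 (11 kb inside) and 63 kb in clr4D (13 kb inside). The Crb3-GFP array differed from the other 3 at the right end of I, with 0.17 against 1.93 to 2.16.

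The swi6-115 arrays ask whether the rixosome needs the HP1 protein Swi6 to occupy heterochromatin. The histone mark was not measured in these cells, so an effect of Swi6 and a change of the mark cannot be told apart. GFP signal fell by 1.77 (SE 0.24) at the pericentromeres, from 1.67 to -0.10 (fry adjusted p = 0.00133), with all 4 proteins lower. It fell by 0.97 (SE 0.10; adjusted p = 0.00065) at the mating-type locus, where 0.55 remained, and by 1.21 (SE 0.20; adjusted p = 0.00143) at the subtelomeres, again with all 4 proteins lower. On the mating-type contig it fell from 2.06 to 0.48 (adjusted p = 0.000339), also in 4 of 4. Among single windows, those at III 1121001 to 1122000 (3.82 to 0.57, difference -3.26, SE 0.29, adjusted p = 3.51e-05), I 3761001 to 3762000 (-3.25, adjusted p = 2.51e-05) and II 1609001 to 1610000 (-3.23) fell furthest. The window at 29001 to 30000 of the mating-type contig fell by 3.19. In all, 573 of 12411 windows changed, 506 down and 67 up, and 569 of them moved the same way with all 4 proteins. Falls covered 34 of 47 windows in cen1, 28 of 31 in cen2, 27 of 34 in cen3, 19 of 30 in the mating-type locus, 43 of 49 at the left end of I, 48 of 48 at its right end, 23 of 37 and 35 of 49 at the left and right ends of II, and 48 of 194 in the distal subtelomeres. The distal subtelomeres averaged -0.25 in WT and -0.46 in swi6-115, so on average they carried no GFP enrichment in WT. The same holds for the left and right ends of II, at -0.09 and 0.02 in WT and -0.70 and -0.54 in swi6-115. Both ends of II enter the subtelomere shift. The ends of III gave no call from limma (0 of 20 and 0 of 15 windows; fry adjusted p = 0.157 and 0.604), within a genome-wide 2127 windows at unadjusted p under 0.05.

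Outside the fixed regions 171 windows fell and 67 rose in swi6-115 among 11819 tested, and the rises were small. In the 30-kb flanks, a test chosen after the data were seen, GFP signal fell by 0.32 at cen1, by 0.25 at cen2, by 0.56 at cen3 and by 0.22 at the mating-type locus (fry adjusted p = 0.000234, 0.000466, 0.000538 and 0.00222). In clr4D it fell there by 0.30, by 0.24, by 0.53 and by 0.24 (adjusted p = 0.000377, 0.000531, 0.000705 and 0.00175). The rises reached 0.53 at III 118001 to 119000 (adjusted p = 0.00863) and 0.47 at III 1592001 to 1593000, with 0.41 at I 4232001 to 4233000 and 0.40 at III 1686001 to 1687000, II 2047001 to 2048000 and III 566001 to 567000. With normexp background correction 195 of 692 calls were up, against 67 of 573 here.

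The clr4D arrays ask the same question of Clr4, the H3K9 methyltransferase. Swi6 binds methylated H3K9, so cells without Clr4 may also lack Swi6 on heterochromatin. These arrays therefore cannot separate a need for the mark from a need for Swi6. H3K9 methylation was not measured in the mutants used for the GFP arrays, so its level there was not checked. GFP signal fell by 1.82 (SE 0.24; fry adjusted p = 0.00104) at the pericentromeres, by 0.98 (adjusted p = 0.000615) at the mating-type locus, by 1.64 (adjusted p = 0.00029) on the mating-type contig and by 1.25 (adjusted p = 0.00129) at the subtelomeres, each with all 4 proteins lower. The left end of III also fell, by 0.79 (adjusted p = 0.0364), while its right end, at -0.32, did not pass (adjusted p = 0.117). The left end of III averaged 0.01 in WT and -0.77 in clr4D. Like the ends of II, it therefore carried on average no GFP enrichment in WT. Of 583 windows that changed, 505 fell and 78 rose, and 577 moved the same way with all 4 proteins. The deepest falls were at II 1609001 to 1610000 (-3.47), III 1121001 to 1122000 (-3.44), II 1640001 to 1641000 (-3.42) and 29001 to 30000 of the mating-type contig (-3.41). The largest rises, at II 457001 to 458000 and II 458001 to 459000 (1.56 in the latter), lie over the interval these strains lack, where the ratio has little extract signal under it. The neighbouring window at II 456001 to 457000 rose by 0.48 and III 1686001 to 1687000 by 0.43.

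Set against each other, clr4D and swi6-115 differed by -0.05 (SE 0.24) at the pericentromeres, and no region passed (fry adjusted p = 0.981 for each). The single window called, at II 458001 to 459000 (1.40, adjusted p = 0.000277), is again over the missing clr4 interval; 330 windows had an unadjusted p under 0.05. With the slide as a block the pericentromere shifts were -1.91 (SE 0.26) for swi6-115 and -1.96 for clr4D, and the calls numbered 657 and 629. Within slides, swi6-115 and clr4D stood below WT by -2.34 and -2.55 for Las1-GFP, -1.70 and -1.68 for Ipi1-GFP, and -1.91 and -1.43 for Crb3-GFP; for GFP-Rix1, whose WT lay on another slide, the differences were -1.13 and -1.64. Without Las1-GFP the swi6-115 count was 361 and without Ipi1-GFP it was 372, and without Ipi1-GFP the clr4D count was 320. The ChIP channel alone dropped by 1.08 (SE 0.088) at the pericentromeres in swi6-115 while the extract channel rose by 0.68 (SE 0.19), so part of the ratio difference stands in the extract.

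**Figure D2:**
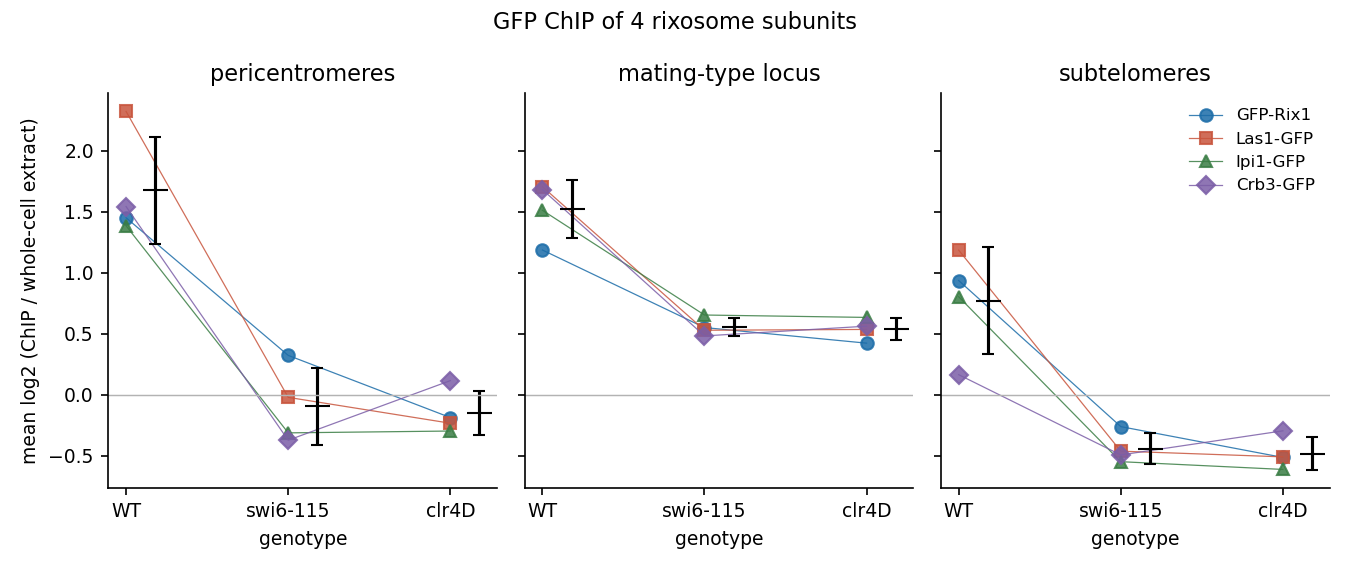
Mean log2 ratio of ChIP over whole-cell extract (vertical axis) by genotype (horizontal axis) for the 4 tagged proteins at the pericentromeres, the mating-type locus and the subtelomeres. Coloured symbols are single arrays and black bars are the mean with 1 SD (n = 4); the pericentromere mean was 1.67 in WT, -0.10 in swi6-115 and -0.15 in clr4D.

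In WT cells rixosome and H3K9me3 signals were correlated across the windows of the fixed regions. Across 12349 windows the mean WT GFP ratio and the mean WT H3K9me3 ratio had a Pearson r of 0.64 and a Spearman rho of 0.146. In the 578 windows of the fixed regions and mating-type contig r was 0.906 and rho 0.804, and in the rest of the genome 0.26 and 0.136. With swi6-115 GFP arrays r over all windows was 0.00845 and with clr4D -0.0263, although in the 578 windows r was still 0.536 and 0.478. These values depend on the measure. With the ChIP channel alone r over all windows was 0.782 in WT, 0.672 in swi6-115 and 0.664 in clr4D, and with normexp it was -0.111 and -0.139 in the mutants. These correlations are across windows, which are not independent replicates.

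H3K9me3 in WT cells stood at 4.45 over the pericentromeres (3.94 in cen1, 4.07 in cen2, 5.49 in cen3), 3.34 over the mating-type locus, 4.50 on the mating-type contig and 3.39 over the subtelomeres (means of 2 arrays). The mark left a gap over the middle of each centromere, where the central core carries the centromeric histone, and in WT it spread into the flanks. A ratio of at least 1 on both WT arrays covered 681 kb, with 366 kb (53.7%) inside the regions: 36 kb in cen1, 20 kb in cen2, 25 kb in cen3, 30 kb in the mating-type locus and 48 kb at the right end of I. The 30 kb on either side averaged 1.75 at cen1, 1.56 at cen2, 2.38 at cen3 and 1.64 at the mating-type locus. The H3K9me3 mean and enriched extent of the mating-type locus, here and below, take in II 2133000 to 2133960, which all 10 H3K9me3 arrays lacked. Over that interval the WT arrays had ChIP at -6.80 and -4.19 and extract at -8.74 and -8.55. A high ratio there is therefore not evidence of the mark.

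The ago1D arrays ask how much H3K9me3 stays without RNA interference. The mark fell at windows in and beside cen1 and cen3. Some other windows in cen1 and cen3 kept high ratios, although with the slide as a block they fell as well. At I 3758001 to 3759000 the ratio was 7.37 in WT and 5.96 in ago1D. All 30 windows that changed fell: 14 of 47 in cen1, 3 of 33 in cen3 and 13 in the rest, with 442 windows at unadjusted p under 0.05. The window at III 1071001 to 1072000 dropped by 4.85 (SE 0.49, adjusted p = 0.0183), from a WT mean of 6.20, and I 3753001 to 3754000 fell by 4.85, from 5.25 to 0.39 (adjusted p = 0.0298). Beyond the other side of cen3, the differences were -4.39 at III 1140001 to 1141000, -4.36 at III 1141001 to 1142000 (adjusted p = 0.00627) and -4.26 at III 1142001 to 1143000. On the far side of cen1, I 3786001 to 3787000 went from 4.29 to 0.00 and I 3787001 to 3788000 differed by -3.72. In the 30-kb flanks, a test chosen after the data were seen, the mark fell by 1.77 at cen1, to -0.01, and by 1.78 at cen3, to 0.60 (fry adjusted p = 0.0345 for each, 0.0642 and 0.0637 with the slide block). The flanks of cen2 gave -0.47 (adjusted p = 0.365, and 0.0637 with the slide block).

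Averaged over whole regions, H3K9me3 in ago1D was 2.56 at the pericentromeres, a difference of -1.89 (SE 0.58) that did not pass (fry adjusted p = 0.256); cen1 differed by -2.36, cen2 by -1.10 and cen3 by -1.94. The mating-type locus differed by -0.20 (adjusted p = 0.848) and the right end of I stood at 5.19 in ago1D and 3.84 in WT (SE of the difference 0.42; adjusted p = 0.317). A ratio of at least 1 on both ago1D arrays covered 442 kb, with 16 kb left in cen1 against 36 kb in WT, and 109 kb outside all regions against 315 kb in WT. The gap was smaller on single arrays, which covered 956 and 915 kb in WT (366 and 470 kb inside the regions) and 721 and 733 kb in ago1D (335 and 475 kb inside). With the slide as a block, 374 windows changed, among them the 30: all 47 windows tested in cen1, all 33 in cen3 and 16 of 28 in cen2 fell, and 38 of 49 at the right end of I rose, by up to 2.66. Pericentromeres were lower on both slides, by -2.05 on slide 6 and -1.73 on slide 8, and the right end of I was higher on both, by 1.75 and 0.94. The pericentromere difference was -1.64 and -1.53 in the ChIP channel and 0.39 and 0.21 in the extract. The blocked pericentromere shift was -1.89 (SE 0.16; fry adjusted p = 0.132). Leaving out 1 array raised the count in each case, to 64 without WT replicate 2, 102 without WT replicate 1, 202 without ago1D replicate 1 and 240 without ago1D replicate 2.

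Single mutations in amo1, rix1 and pob3 ask whether H3K9me3 is kept when RNA interference is intact. Pericentromeres averaged 3.36 in the array labelled amo1D, 3.28 in rix1E414K and 4.41 in pob3D against 4.45 in WT. The differences, -1.09 (SE 0.71; fry adjusted p = 0.429), -1.17 (adjusted p = 0.437) and -0.04 (adjusted p = 0.986), did not pass. At the mating-type locus the means were 2.24, 2.11 and 2.69 against 3.34, and on the mating-type contig 3.02, 3.08 and 3.83 against 4.50, also without passing. In the array labelled amo1D, 3 windows changed: 23001 to 24000 of the mating-type contig fell by 4.39, from 6.99 to 2.60 (adjusted p = 0.0148), and II 3031001 to 3032000 (5.24) and II 3030001 to 3031000 (4.06) rose over the amo1 interval that its extract lacks. Under normexp, and with the ChIP channel alone, limma called 0 windows for it, with 76 and 18 at unadjusted p under 0.05. In rix1E414K limma called 0 windows, with 177 at unadjusted p under 0.05; the most extreme were 23001 to 24000 of the mating-type contig (-4.05, adjusted p = 0.0708), III 116001 to 117000 (-3.25, adjusted p = 0.348), mating-type contig 24001 to 25000 (-2.94), I 2522001 to 2523000 (1.40), II 2340001 to 2341000 (1.21) and II 3394001 to 3395000 (1.15). In pob3D limma called 0 windows, with 169 at unadjusted p under 0.05; the most extreme were III 8001 to 9000 (-2.57), III 2445001 to 2446000 (-2.56), II 1475001 to 1476000 (-2.48), III 229001 to 230000 (2.12), I 2914001 to 2915000 (1.82) and I 2023001 to 2024000 (1.69), each at adjusted p = 1.

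With the slide as a block, 5 windows fell in rix1E414K, 4 of them on the mating-type contig, and in pob3D 23 fell and 1 rose, with 4 falls each in cen3, the mating-type contig and the right end of I. Blocked pericentromere shifts were -0.77 (SE 0.21) and -0.44 (SE 0.21), and on their own slides the differences from WT were -0.85 and -0.37. At the mating-type locus the differences on those slides were -0.86 and -1.01. The array labelled amo1D shares no slide with WT, so its genotype and slide 7 cannot be told apart, and each direction drawn from it carries the disagreement between its extract and its ChIP. Without ago1D replicate 1, counts were 62, 21 and 31 for amo1D, rix1E414K and pob3D, and without ago1D replicate 2 they were 61, 21 and 31; without WT replicate 1 amo1D had 5 and rix1E414K 7, and without WT replicate 2 they had 5 and 1.

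In cells that lacked Ago1, windows across all 3 pericentromeres had less H3K9me3 with each of the 3 second mutations, each on 1 array. For amo1D-ago1D the difference from ago1D cannot be told apart from slide 7. The pericentromere mean was 2.56 in ago1D and -0.66 in amo1D-ago1D, -0.53 in rix1E414K-ago1D and 0.19 in pob3D-ago1D. The window at II 1619001 to 1620000 in cen2 went from 6.07 to -1.26 in amo1D-ago1D, a fall of -7.32 (SE 0.45, adjusted p = 0.000447), and its differences were -7.24 in rix1E414K-ago1D (adjusted p = 0.000471) and -6.52 in pob3D-ago1D (adjusted p = 0.00132). In cen1, I 3758001 to 3759000 differed by -7.11, -7.00 and -6.46, and in cen3, III 1092001 to 1093000 by -6.51, -6.65 and -5.50, all past the threshold. A ratio of at least 1 covered 18 kb of cen2 in ago1D and 2 kb in each double mutant, 20 kb of cen3 against 7, 7 and 6 kb, and 16 kb of cen1 against 4, 7 and 7 kb. The left end of chromosome I stood at 4.94, 4.77 and 4.87 against 5.09 in ago1D, and 47, 46 and 47 of its 47 windows had a ratio of at least 1. The right end stood at 3.44, 3.84 and 3.73 against 5.19 in ago1D and 3.84 in WT, without passing over the region (fry adjusted p = 0.207, 0.283 and 0.316). On the shared slides rix1E414K-ago1D and pob3D-ago1D differed there from ago1D by -1.33 and -1.47.

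Counted over windows, amo1D-ago1D differed from ago1D at 67 (66 down), rix1E414K-ago1D at 72 (68 down) and pob3D-ago1D at 49 (all down). Falls covered 14, 14 and 12 windows in cen1, 15, 18 and 13 of 28 in cen2, and 21, 21 and 19 of 33 in cen3, with 9, 7 and 3 of 36 on the mating-type contig. The rix1E414K-ago1D array also fell at 4 of 30 windows in the mating-type locus and amo1D-ago1D at 3 at the right end of I. Averaged over the pericentromere probes the differences were -3.22 (SE 0.71), -3.09 and -2.37. None passed with fry, which used the 108 pericentromere windows (adjusted p = 0.17, 0.132 and 0.287). At the mating-type locus they were -1.34, -1.48 and -1.36, leaving 1.80, 1.65 and 1.78, and the subtelomeres differed by -0.60, -0.67 and -0.50. The rises were few. In rix1E414K-ago1D, II 2199001 to 2200000 rose by 2.61, II 2200001 to 2201000 by 3.88 (adjusted p = 0.0296), II 2201001 to 2202000 by 3.86 and III 1038001 to 1039000 by 2.34; in amo1D-ago1D, II 3031001 to 3032000 rose by 2.15 over the missing amo1 interval.

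With the slide as a block, rix1E414K-ago1D gave 129 windows (115 down) and pob3D-ago1D 303 (all down), which took in all 72 and all 49 of the calls without it. In pob3D-ago1D the falls then covered 25 of 30 windows in the mating-type locus, 31 of 36 on the mating-type contig and 35 of 49 at the right end of I, and in rix1E414K-ago1D 12, 16 and 11. Blocked pericentromere shifts were -2.69 (SE 0.21) and -2.77 (fry adjusted p = 0.124 and 0.128). The flanks of cen2 differed by -1.06 and -1.62 with the block (adjusted p = 0.0497 and 0.0418) and by -1.30 and -1.38 without it (0.254 and 0.21). At the pericentromeres the differences from ago1D on the shared slide were -2.61 and -2.85. Of these, the ChIP channel carried -1.69 and -1.80 and the extract 0.90 and 1.04 the other way. The amo1D-ago1D array shares slide 7 with the array labelled amo1D only and stood -4.02 below it at the pericentromeres (-2.94 in the ChIP channel, 1.08 in the extract). Without WT replicate 1, WT replicate 2, ago1D replicate 1 and ago1D replicate 2 in turn, the counts were 133, 132, 465 and 166 for amo1D-ago1D, 111, 110, 493 and 112 for rix1E414K-ago1D, and 108, 107, 198 and 139 for pob3D-ago1D. With spread scaling between arrays limma called 0 windows in each of the 3 comparisons and in ago1D against WT, with 104, 72, 186 and 266 windows at unadjusted p under 0.05. With the ChIP channel alone limma also called 0 in each, with 196, 167, 161 and 267 at unadjusted p under 0.05. Its pericentromere differences were -2.25, -2.42, -1.07 and -1.59. With the slide block added it called 212 windows for rix1E414K-ago1D, 396 for pob3D-ago1D and 392 for ago1D, among them all 14, 10 and 10 picked by the naming rule.

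**Figure D3:**
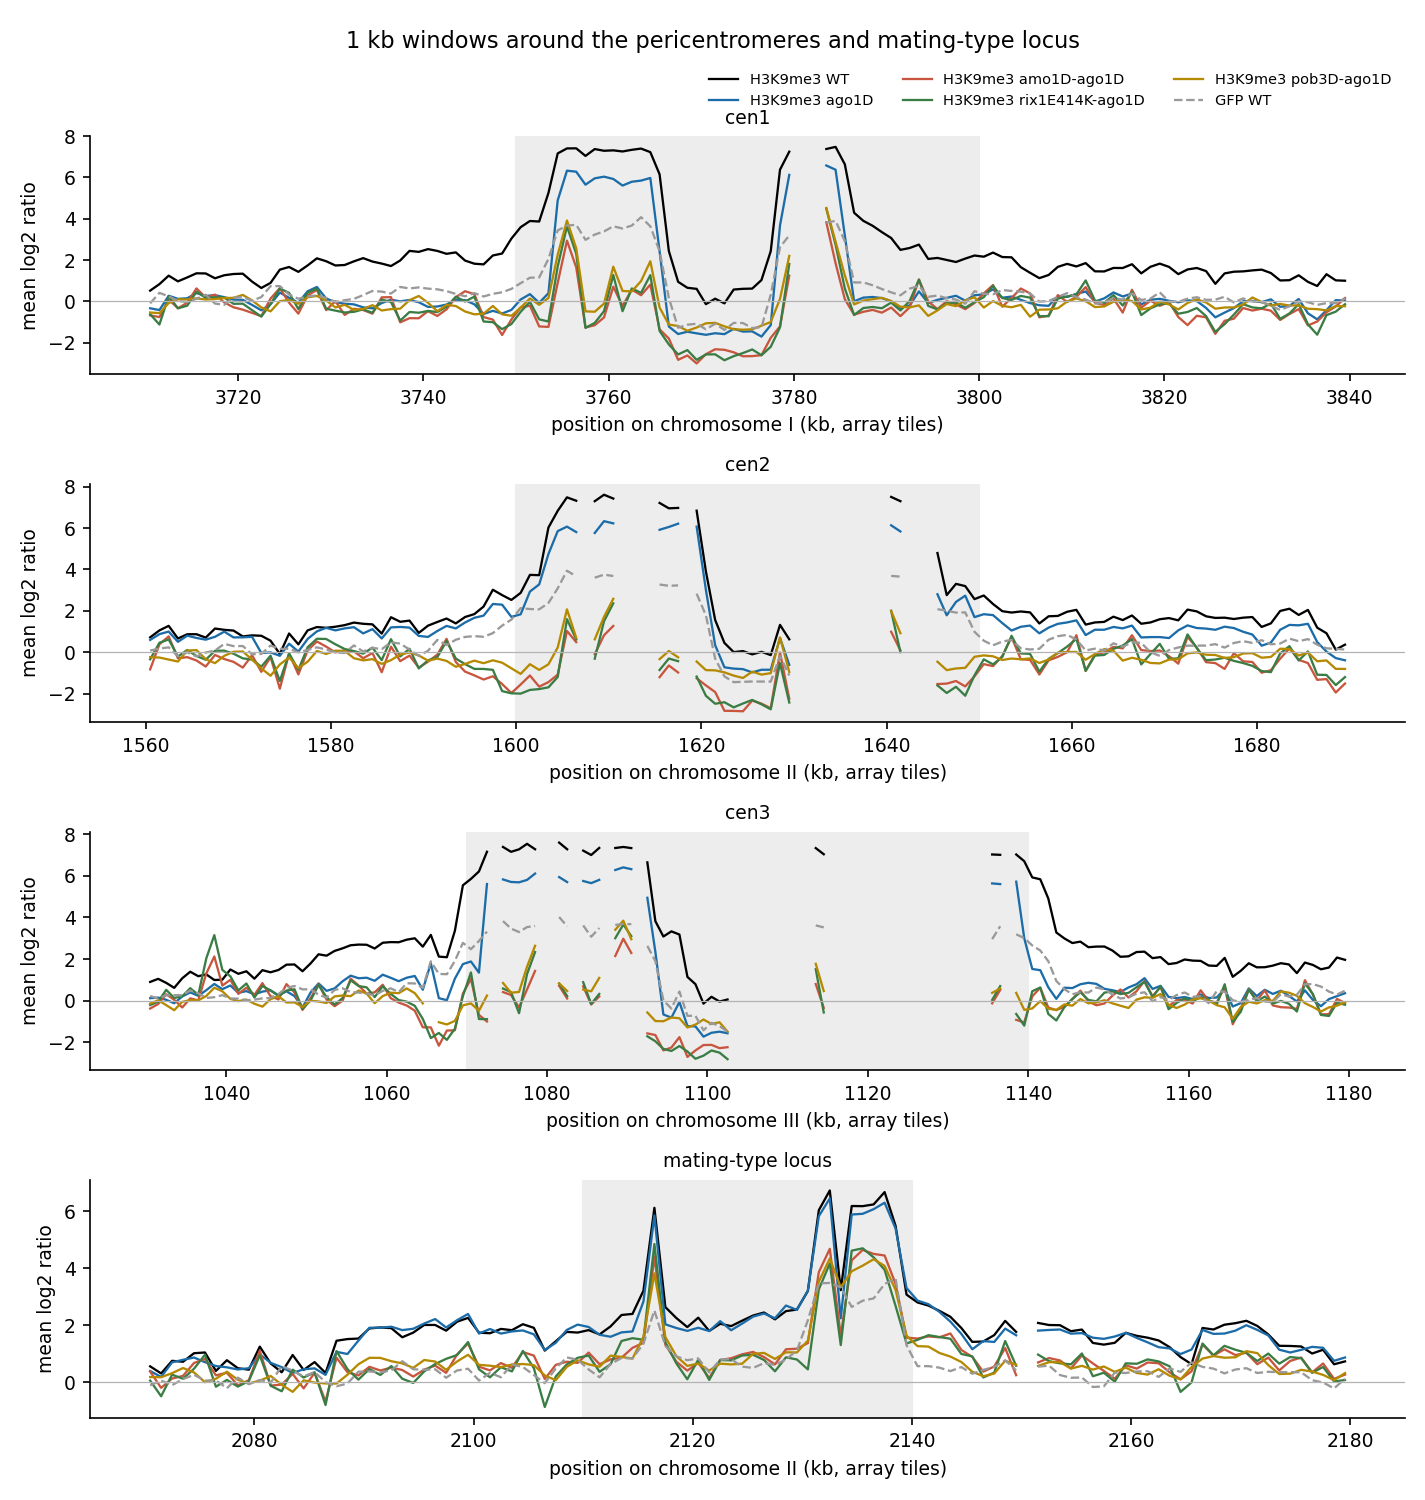
Mean log2 ratio of ChIP over whole-cell extract in 1-kb windows (vertical axis) along the tile positions in kb (horizontal axis) around cen1, cen2, cen3 and the mating-type locus; grey shading marks the fixed region, solid lines are H3K9me3 means per genotype and the dashed line is the mean of the 4 WT GFP arrays. Gaps are windows without values on every array; at cen1 the ago1D line falls to 0.00 at I 3786001 to 3787000, where WT stands at 4.29.

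Whether the second mutation changes the log2 ratio more in ago1D than in otherwise wild-type cells was tested as an interaction. This concerns fold changes, and differences of linear ratios were not tested. All windows called were more negative in the ago1D background, and all lay in the pericentromeres: 9 for amo1D (3 in cen1, 4 in cen2, 2 in cen3), 17 for rix1E414K (6, 6 and 5) and 30 for pob3D (8, 8 and 14). At unadjusted p under 0.05 there were 155, 83 and 126 windows. The most negative were II 1619001 to 1620000 for amo1D (-6.00, SE 0.64, adjusted p = 0.0265), I 3758001 to 3759000 for rix1E414K (-5.89, adjusted p = 0.0321) and II 1617001 to 1618000 for pob3D (-6.37, adjusted p = 0.0132). Over whole pericentromeres the interactions were -2.13, -1.92 and -2.33, without passing (fry adjusted p = 0.459, 0.776 and 0.66). With the slide as a block 95, 59 and 70 windows were called, among them all 9, 17 and 30, and the pericentromere interactions had an SE of 0.28 (fry adjusted p = 0.133, 0.24 and 0.26). Not all blocked calls were negative or pericentromeric. For amo1D, windows at the ends of III rose, by up to 3.36 (left) and 3.15 (right), and others in the rest by up to 3.32. For rix1E414K, windows in the rest rose by up to 3.56. The left end of III averaged 4.63 in amo1D-ago1D, 2.90 in ago1D, 1.73 in the array labelled amo1D and 2.79 in WT. It also averaged 4.09 in rix1E414K-ago1D and 2.20 in rix1E414K, and 2.43 in pob3D-ago1D and 1.24 in pob3D. No window there was called in the blocked rix1E414K or pob3D interaction. In the flanks of cen2 the interactions were -0.96, -0.69 and -1.45 (fry adjusted p = 0.0351, 0.038 and 0.061 with the block, and 0.889, 0.697 and 0.337 without it). The amo1D interaction draws its direction in part from the array labelled amo1D, and normexp background correction ended its calls and those for rix1E414K (limma, 0 windows each, 136 and 88 at unadjusted p under 0.05). Spread scaling and the ChIP channel alone ended the calls of all 3 interactions (limma, 0 windows each). There were 33, 8 and 69 windows at unadjusted p under 0.05 after scaling and 44, 20 and 55 in the ChIP channel. With the slide block added, the ChIP channel alone called 77, 38 and 88 windows, among them all 9, 10 and 10 picked by the naming rule. Without WT replicate 1, WT replicate 2, ago1D replicate 1 and ago1D replicate 2 in turn, the counts were 53, 44, 123 and 88 for amo1D, 29, 38, 73 and 43 for rix1E414K, and 41, 55, 77 and 57 for pob3D.

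**Figure D4:**
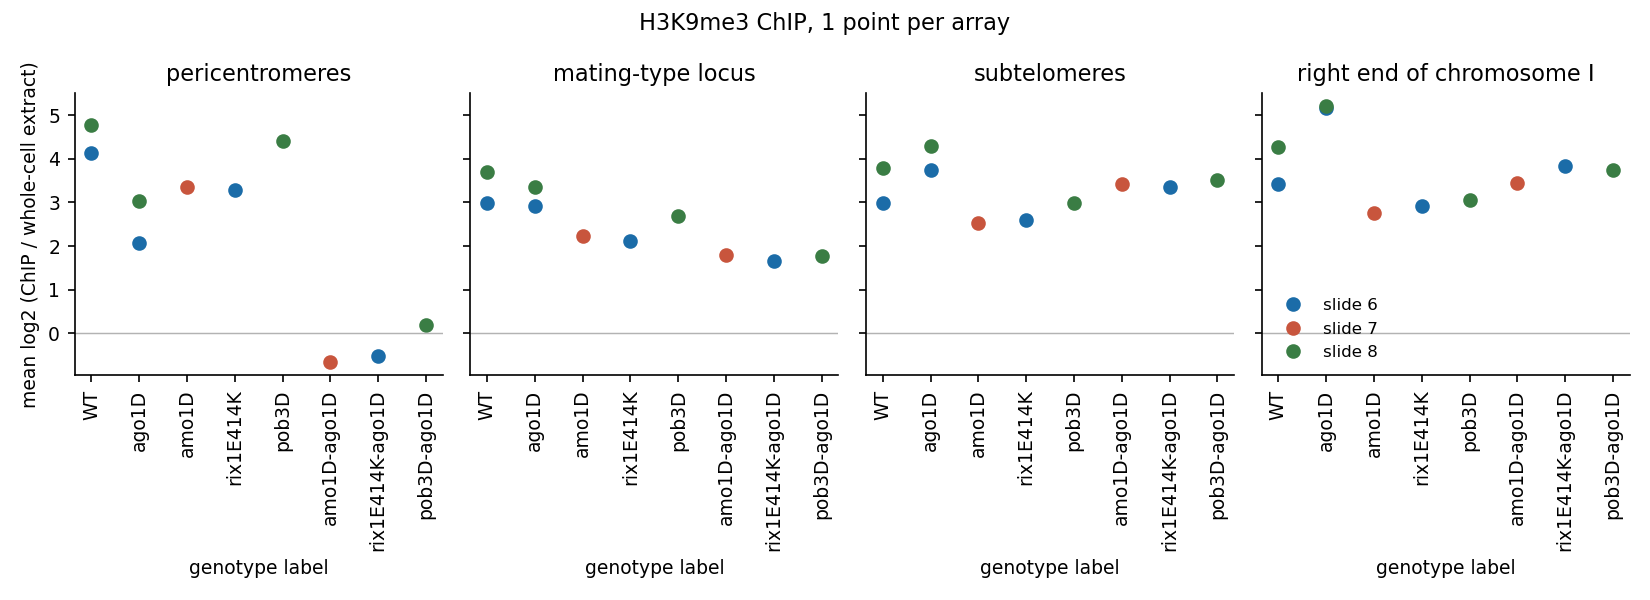
Mean log2 ratio of H3K9me3 ChIP over whole-cell extract (vertical axis) per array and genotype label (horizontal axis) at the pericentromeres, the mating-type locus, the subtelomeres and the right end of chromosome I, with 1 point per array coloured by slide. The 3 double mutants stand between -0.66 and 0.19 at the pericentromeres, below both ago1D arrays.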

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

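The tests of explanations in this part, the splits of arrays included, were chosen after the results were seen; the interaction tests were not.

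The array labelled amo1D kept ChIP signal at the amo1 interval, II 3030300 to 3031860, where its whole-cell extract had lost it. ChIP DNA from cells with an intact amo1 may account for this, because the ChIP channel stood at -0.57, inside the range of the 20 arrays without the loss (-0.83 to -0.32), whereas signal from spots without target DNA was argued against, since the highest ChIP channel among the other 24 combinations with lost extract was -4.19. ChIP DNA from one of the GFP strains was argued against too, since at the mating-type interval missing from all H3K9me3 arrays its ChIP channel was -5.60, where the lowest GFP array had 0.21. A strain without ago1 or without pob3 was argued against by ChIP channels of -0.0355 over the ago1 interval and 0.13 over the pob3 interval, where the highest arrays with those losses had -4.69 and -7.31. Where the ChIP DNA came from stays open, including whether it came from a strain of this series at all. Whether the values of this array, and the 9 windows of the amo1D interaction, describe cells without Amo1 stays open too.

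GFP ratios at the pericentromeres were lower in swi6-115 and clr4D than in WT, and part of that difference lay in the extract channel, which rose by 0.68 and 0.73 while ChIP fell by 1.08 and 1.07. A difference in the extract alone was argued against by the ChIP channel difference of -1.08 (SE 0.088) in swi6-115. Competition of ChIP DNA and extract DNA for the same spots could lower the extract signal where ChIP signal is high. Between the WT H3K9me3 arrays, however, the one with more pericentromeric ChIP signal (by 1.35) also had more extract signal, by 0.65, and between the ago1D arrays the differences were 1.47 and 0.46. These are only 2 pairs, both split over slides 6 and 8, so competition and the slide cannot be told apart, and a different recovery of heterochromatic DNA in the extract was not tested.

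The counts of changed windows were also set against other groupings of the 8 GFP arrays. The tagged proteins pair these arrays, and only 8 splits keep 1 array of each protein on either side, which is too few for a share under 0.05. Among them 1 of 8, the real one, reached 573 windows for swi6-115 against WT, 583 for clr4D against WT and 1 for clr4D against swi6-115, and the highest other split gave 0 in each. Over all 35 splits, which mix proteins, the highest other gave 0, 3 and 1.

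Single arrays stood apart from the 3 others of their genotype in 6 of 51 groups by Dixon's test, which chance meets in about 1 in 20 independent groups. These groups are regions of the same 12 arrays and some contain others, so their number says nothing about chance. Las1-GFP in WT had 3.16 at cen3 against 1.98 to 2.07, 2.32 over the pericentromeres against 1.38 to 1.54, and 0.00737 in the rest of the genome against 0.0276 to 0.0316. Crb3-GFP in WT had 0.17 at the right end of I against 1.93 to 2.16. Crb3-GFP in clr4D had 0.26 at cen3 against -0.18 to -0.14, and -0.0366 at the left end of I against -0.32 to -0.30.

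The effect of a second mutation on the log2 ratio differed between ago1D and otherwise wild-type cells. This held at 9 windows for amo1D, where the array labelled amo1D enters, at 17 for rix1E414K and at 30 for pob3D. Tiles named pNSU, which enter no comparison, carried a mean GFP ratio of 1.95 in WT, 0.80 in swi6-115 and 0.64 in clr4D (n = 4 arrays each); what these tiles represent is not given in the sources used here.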

How the results depend on the processing

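The ChIP channel alone, its combination with the slide block, and the removal of windows over lost extract were chosen after seeing the data, as was removal of the array labelled amo1D, which left every count of the other comparisons as it was. A shift that passes under neither setting counts as kept, and no H3K9me3 pericentromere shift passed in the main fit. For H3K9me3 the number kept therefore says little about robustness. Of 586 shifts of the fixed regions under other settings, flanks not counted, 583 kept their side of the threshold, 3 passed it newly and 0 reversed after passing. Signs turned in 30 that did not pass. The 3 arose with the ChIP channel alone and the slide block, namely the rix1E414K interaction at the pericentromeres (-1.16, adjusted p = 0.00852) and pob3D-ago1D at the pericentromeres (-1.77, adjusted p = 0.00838) and the mating-type locus (-1.44, adjusted p = 0.0465). The flanks were refitted with the slide block only: of 44 tests 38 kept their side, ago1D at cen1 and cen3 no longer passed (adjusted p = 0.0642 and 0.0637), and cen2 passed newly in rix1E414K-ago1D (-1.06, adjusted p = 0.0497), pob3D-ago1D (-1.62, 0.0418) and the amo1D and rix1E414K interactions (-0.96, 0.0351, and -0.69, 0.038). Among the 38 flank tests that kept their side, 30 passed in neither fit and 8, all of GFP, passed in both. Of 222 other values, 114 stayed the same and 108 moved, and the cause was not tested except where the setting itself shows it. Under normexp, swi6-115 had 692 windows with 195 up (67 of 573 without it) and clr4D 605 with 106 up, while limma called 0 windows for clr4D against swi6-115 (244 at unadjusted p under 0.05), 0 for amo1D (76), 0 for the amo1D interaction (136) and 0 for the rix1E414K interaction (88), and the correlation across windows with H3K9me3 became -0.111 for swi6-115 and -0.139 for clr4D. Without centring, clr4D against swi6-115 had 2. With spread scaling limma called 0 for ago1D (266 unadjusted), 0, 0 and 0 for the amo1D, rix1E414K and pob3D double mutants (104, 72 and 186), and 0, 0 and 0 for their interactions (33, 8 and 69). Restricting to probes well above background left 0 windows for clr4D against swi6-115 (332 unadjusted with limma) and 1 for amo1D. Windows of 3 kb, which are fewer, gave 269 for swi6-115, 285 for clr4D, 14 for ago1D, 1 for amo1D, 32, 38 and 28 for the double mutants, 3 for the amo1D interaction and 19 for the pob3D interaction, with a correlation of 0.738 across windows in WT. The ChIP channel alone gave 2 for clr4D against swi6-115, and with limma 0 for ago1D (267 unadjusted), 0 for amo1D (18), 0, 0 and 0 for the double mutants (196, 167 and 161) and 0, 0 and 0 for the interactions (44, 20 and 55); its correlations with H3K9me3 across windows were 0.782 in WT, 0.672 in swi6-115 and 0.664 in clr4D. Without the protein term, swi6-115 had 285 and clr4D 291. With 1 protein left out, which removes 3 arrays, swi6-115 ranged from 361 (without Las1-GFP) to 555, clr4D from 320 (without Ipi1-GFP) to 435 and clr4D against swi6-115 from 1 to 2. With the slide as a block, ago1D had 374, rix1E414K 5, pob3D 24, rix1E414K-ago1D 129, pob3D-ago1D 303 and the interactions 95, 59 and 70. Replicate numbers of WT and ago1D coincide with slides 6 and 8, and deviations of same-numbered arrays correlated at 0.675 over 12380 windows; a paired fit of these 4 arrays with the replicate as a block gave 378 windows for ago1D, against 30. With the ChIP channel alone and the slide block, ago1D had 392, rix1E414K 1, pob3D 88, rix1E414K-ago1D 212, pob3D-ago1D 396 and the interactions 77, 38 and 88. Without windows over lost extract, limma called 0 for clr4D against swi6-115 (327 unadjusted) and 1 for amo1D. With 1 WT or ago1D array left out, the lone array of that genotype is assumed to vary like the remaining pair, 1 residual degree of freedom is left, and the prior degrees of freedom rise from 5.69 to 30.8 or more. The counts then ran from 64 (without WT replicate 2) to 240 (without ago1D replicate 2) for ago1D, 5 to 62 for amo1D, 1 to 21 for rix1E414K, 0 (limma, 155 and 282 unadjusted without a WT array) to 31 for pob3D, 132 to 465 for amo1D-ago1D, 110 to 493 for rix1E414K-ago1D, 107 to 198 for pob3D-ago1D, and 44 to 123, 29 to 73 and 41 to 77 for the interactions, the highest from amo1D-ago1D on without ago1D replicate 1. At the lower ratio threshold of 0.58, enriched windows covered 199 kb for GFP in WT, 103 kb in swi6-115 and 63 kb in clr4D, and 703 kb for H3K9me3 in ago1D; at the higher threshold they covered 0 kb in swi6-115, 0 kb in clr4D and 418 kb for H3K9me3 in WT, as a stricter or looser threshold must move them. Gene values, gene lists and the restriction to uniquely matching probes were not run, because no build is named. The H3K9me3 comparisons rest on few arrays, and slide differences add to their spread, since the SE of the ago1D pericentromere shift was 0.58 without and 0.16 with the slide block. Signal over background was 36.7 or more on every array in both channels, and what it limits was not tested.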

Other observations

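The peaks, the rule that picked them and the tests in this part were chosen after the data were seen. More than 30 kb from the fixed regions, H3K9me3 in WT formed 20 isolated peaks of at least 2 adjacent windows with a ratio of at least 1 on both arrays, and the 5 with the highest WT mean differed in how they stood in the mutants. At III 275 to 277 kb the mark was high on every array, with 5.36 in WT, 4.74 in ago1D and 3.97 to 5.48 over the mutants with 1 array, and the rixosome GFP mean was 1.95 in WT, 0.46 in swi6-115 and 0.42 in clr4D. At I 4907 to 4909 kb H3K9me3 was 3.45 in WT and 2.91 in ago1D, with GFP at 1.51 in WT, 0.68 in swi6-115 and 0.67 in clr4D. A pair of other peaks had ratios near 0 on both arrays without Pob3. At II 1473 to 1476 kb H3K9me3 was 2.10 in WT and 2.40 in ago1D, with 0.17 in pob3D, -0.19 in pob3D-ago1D, 1.16 in the array labelled amo1D, 0.92 in amo1D-ago1D, 1.56 in rix1E414K and 2.44 in rix1E414K-ago1D. At I 4530 to 4532 kb it was 2.01 in WT and 2.83 in ago1D, with -0.05 in pob3D, 0.11 in pob3D-ago1D, 0.74 in the array labelled amo1D, 0.07 in amo1D-ago1D, 1.03 in rix1E414K and 1.97 in rix1E414K-ago1D. These values rest on 1 array per mutant, and the calls depend on the slide block. At II 1475001 to 1476000 pob3D differed from WT by -2.48 without it (limma adjusted p = 1) and by -2.31 with it (adjusted p = 0.0466), and pob3D-ago1D from ago1D by -3.30 (adjusted p = 0.0245) and -3.12 (adjusted p = 0.000991). At I 4530001 to 4531000 pob3D missed the threshold both ways (-2.37, adjusted p = 1, and -2.48, adjusted p = 0.0713), while pob3D-ago1D differed by -2.93 (adjusted p = 0.098) and, with the block, by -3.04 (adjusted p = 0.00569). At III 116001 to 117000, in the highest peak, amo1D-ago1D and rix1E414K-ago1D differed from ago1D by -3.15 and -3.69 (adjusted p = 0.0159 and 0.00644). With the block rix1E414K and pob3D also differed there from WT, by -3.17 and -2.32 (adjusted p = 0.0162 and 0.0456).

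The highest isolated peak, at III 115 to 117 kb, stood at 5.43 in WT (5.10 and 5.76 on the 2 arrays) and 5.28 in ago1D. It stood at 2.47 in the array labelled amo1D, 2.85 in rix1E414K and 3.70 in pob3D, and at 2.67, 2.23 and 3.39 in the amo1D, rix1E414K and pob3D double mutants, while GFP means were 2.06 in WT, 0.18 in swi6-115 and 0.11 in clr4D. The signal may come from heterochromatin formed in place on chromosome III, or from DNA of another heterochromatic position that these tiles also match. Heterochromatin in place could spread to the sides, yet the flanks in WT averaged -0.39; flanks of the other 4 peaks were also below 1, between -0.40 and 0.55, so a sharp edge does not decide. Without probe sequences these explanations cannot be told apart, and no gene is named for the interval here.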
